A study of Mus musculus with 7 samples.

How the data were processed

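RNA was made, per the labels' protocols, from cells sorted from CD1 mouse mammary rudiments at E17.5, with Illumina TruSeq RNA kits, and sequenced as 100-base paired ends on a HiSeq2000 in duplicate lanes. Per the submitters' processing notes, reads were aligned with STAR to GRCm38/mm10 and Cufflinks produced the values, with no versions given. The deposited values are FPKM per the file headers, with 1 column per library, and the groups were read from the column names and labels. All 7 columns were used. The labels' growth text also describes a Sox10 overexpression experiment, whose samples are not analysed here. The label of Sox10+EpCAM+ fMaSC replicate 1 does not mention lineage-negative sorting, while its column name does.

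The table holds 38579 gene entries, besides 8 added sequences (reporters and spike-ins) that were left out of the tests. Of the entries, 36664 (95.0%) were named from GENCODE vM21, 25 carry repeated identifiers and were kept apart, and 94.8% of loci overlap the reference locus. Library depth was estimated from FPKM values that correspond to few fragments on transcripts of 800 to 6000 bases. Between 54.7% and 63.9% of these lay within 0.15 of a whole number, so the depths are approximate. A single fragment on a transcript of 2 kb corresponds to 0.01495 to 0.02213 FPKM, and summed FPKM ran from 378952 to 752737 per library.

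The groups, tests, gene lists, named-gene rule and most alternative settings were fixed before the data were examined. FPKM was transformed to log2(FPKM + 1), a scale that understates the change of genes with low values, and genes with 1 FPKM or more in at least 2 of the 7 libraries were kept (14418). Limma 3.58.1 in R 4.3.3 fitted the 4 group means with an empirical Bayes trend and 3 residual degrees of freedom. Tests were two-sided with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The pooled comparison fitted cell type plus strategy, and the difference between strategies was the contrast of both fMaSC-stroma folds. Since the values are FPKM, count-model alternatives were not run. The EpCAM-negative group is a single library, so its variance comes from the other groups. Replicate numbers follow the order of the series, and the labels pair no libraries.

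The 23 gene lists were sort markers, luminal epithelium, basal epithelium, epithelial junction and identity, mammary progenitor-linked, embryonic mammary signalling, mesenchymal transcription and EMT, fibroblast and matrix, adipocyte lineage, glia with neural crest and melanoblast, endothelium, leukocyte, erythroid, skeletal muscle, pericyte, epidermis and hair follicle, proliferation, immediate early and stress response, glycolysis and hypoxia, Wnt pathway, FGF and ErbB pathways, sex-linked, and reference genes. Of their 293 genes 3 are absent by name. Each list was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison, and its members were also adjusted over the list alone. With an estimated correlation camera draws on the residual degrees of freedom, 3 here or 4 in the pooled comparison, and so has little power. Named genes were the sort markers, up to 10 genes per direction with the largest folds (called, libraries of both groups not overlapping, 5 FPKM or more in the higher group, no provisional gene names), and up to 4 members per list. For the difference between strategies, libraries not overlapping meant the fold of each Sox10+EpCAM+ library lying beyond every pairwise CD24-strategy difference, with 5 FPKM or more in the highest group. Genes named outside this rule are said to be so in the text.

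The fit was tested on simulated data with the same groups, 14418 genes and 150 changed genes per size, summed over repeated runs. Noise was drawn independently for each gene, so trends shared by many genes of a library were not simulated. Of genes changed by 1 on the log2 scale, 57.3% were recovered for CD24+CD49f+ fMaSC against CD24low stroma, 31.3% for Sox10+EpCAM+ fMaSC against EpCAM-negative stroma, 85.3% for the pooled comparison, 61.3% between the fMaSC fractions, 24.7% between the stroma fractions and 5.33% for the difference between strategies. Of genes changed by 2, between 80% and 97.3% were recovered. False calls per comparison averaged 4.67 to 10.3 in a single run, which held only part of the 150 changed genes per size. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.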

Results

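RNA was sequenced from mouse fetal mammary cells at E17.5 (a day of gestation), in 7 libraries of freshly sorted primary cells of the CD1 strain, which the labels call biological replicates. A pair of sorting strategies was examined, each yielding a fraction called fetal mammary stem cells (fMaSC, a population enriched for them) and a stromal fraction. Sorting on CD24 and CD49f gave 2 CD24+CD49f+ fMaSC libraries and 2 CD24low stroma libraries, all labelled lineage-negative. Sorting on a Sox10-Venus fluorescent reporter and EpCAM gave 2 Sox10+EpCAM+ fMaSC libraries and 1 EpCAM-negative stroma library, so that this last group has no replicate and no SD. The column names give all libraries of this sort as lineage-negative, and the stroma library as Sox10-negative too. Levels of Epcam, Sox10 and genes of other Sox10-bearing cells in these fractions are therefore partly set by the sort. The deposited values are FPKM without counts. An estimate from the lowest values put 22.6 M to 33.5 M fragments behind each library, and 12790 to 13639 genes reached 1 FPKM. Mitochondrial genes took between 6.23% of the summed FPKM (EpCAM-negative stroma) and 19.0% (Sox10+EpCAM+ fMaSC replicate 1). Across genes, which are not independent replicates, the log2 values of replicates correlated with Pearson's r of 0.987 for Sox10+EpCAM+ fMaSC, 0.936 for CD24+CD49f+ fMaSC and 0.969 for CD24low stroma. The EpCAM-negative library correlated with the CD24low stroma libraries at 0.974 and 0.963.

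The genes that encode the sorting markers were examined first. Epcam (ENSMUSG00000045394, chromosome 17, 87635979 to 87651106 of GRCm38) encodes an adhesion molecule of epithelial cells. Its mean level was 225 ± 7.73 FPKM (SD, n = 2) in Sox10+EpCAM+ fMaSC, 113 ± 34.4 (SD, n = 2) in CD24+CD49f+ fMaSC, 0.48 ± 0.074 (SD, n = 2) in CD24low stroma and 1.19 in EpCAM-negative stroma. Sox10 (ENSMUSG00000033006, chromosome 15, 79154913 to 79164490), a transcription factor of neural crest, glia and mammary epithelium, stood at 107 ± 4.88, 58.3 ± 0.516, 1.2 ± 0.496 and 0.493 FPKM in the same order of groups. Cd24a (ENSMUSG00000047139, chromosome 10, 43579169 to 43584262), which encodes the surface glycoprotein CD24, stood at 389 ± 14.2, 203 ± 60.4, 9.04 ± 4.33 and 6.79 FPKM. Itga6 (ENSMUSG00000027111, chromosome 2, 71745616 to 71858416) encodes the integrin CD49f and stood at 130 ± 21.9, 88.6 ± 16.1, 21.4 ± 1.25 and 19.6 FPKM.

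**Figure D1:**
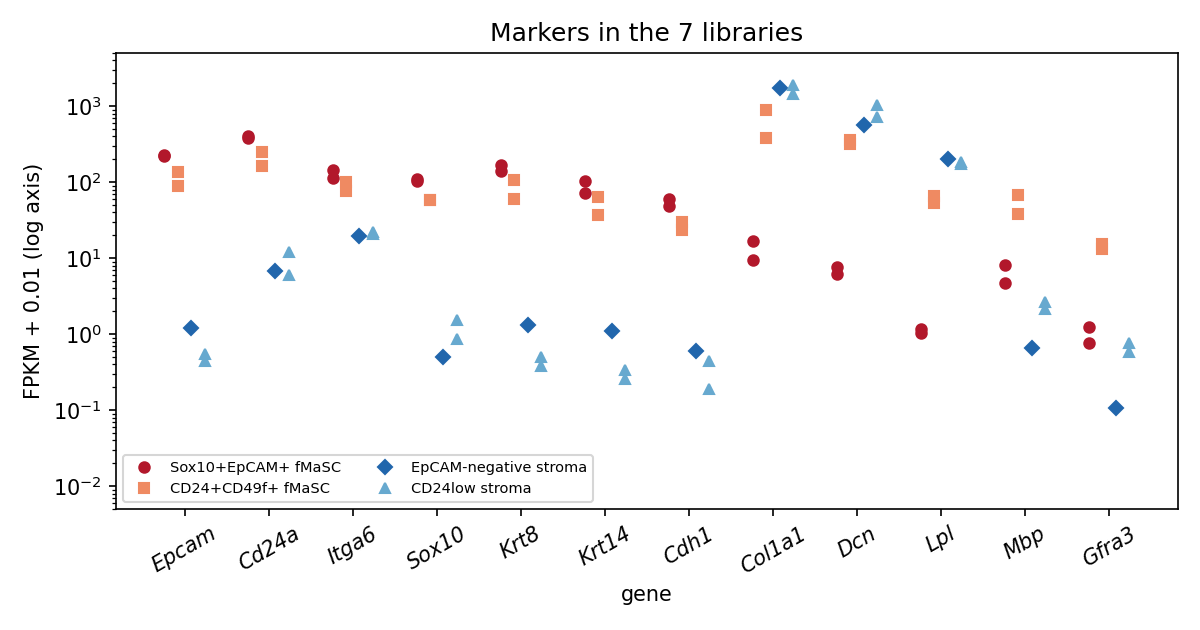
FPKM plus 0.01 (log axis) of 12 sorting, epithelial, stromal and glial genes in each of the 7 libraries, 1 point per library, coloured by group. Epithelial genes stand high in the 4 fMaSC libraries, Col1a1, Dcn and Lpl stand high in the 3 stroma libraries and at intermediate levels in the CD24+CD49f+ fMaSC libraries, and Mbp and Gfra3 are highest in the CD24+CD49f+ libraries.

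The first comparison asked what separates the epithelial from the stromal fraction in the CD24 and CD49f sort. Epithelial genes such as Krt8 and Cldn6 were higher in CD24+CD49f+ fMaSC than in CD24low stroma, and genes such as the matrix gene Efemp1 and the lipase gene Lpl were lower. Csn3, which encodes kappa-casein, had the largest rise, to 148 ± 115 FPKM (SD, n = 2) from 0.621 ± 0.0888, a log2 fold change of 6.27 (SE 0.54, limma adjusted p = 0.00178). Epcam followed at 6.23 (SE 0.24, adjusted p = 0.000356). Krt8 and Krt18, the paired keratins of simple epithelium, rose by 5.83 and 5.61, and Krt14, a keratin of basal epithelial cells, by 5.27 (adjusted p = 0.00051 or lower). Cytl1, a secreted cytokine-like protein, rose by 5.83, Igfbp2, which binds insulin-like growth factors, by 5.30, Col9a3, a chain of collagen IX, by 5.25, the protease inhibitor gene Spint2 by 5.12 and Plet1, a surface protein of epithelial progenitors, by 5.11 (adjusted p = 0.00119 or lower). Sox10 and Cd24a rose by 4.77 and 4.39. All of these calls were kept whichever library was left out. Itga6 rose by 1.99 (adjusted p = 0.00469), a call that ended without CD24low stroma replicate 2 (adjusted p = 0.0557).

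Among the genes lower in CD24+CD49f+ fMaSC, several are known from mast cells. The protease genes Cpa3 (−3.10), Tpsb2 (−2.92), Cma1 (−2.91) and Tpsab1 (−2.40) and Hdc (−2.63), which encodes the enzyme that makes histamine, had adjusted p between 0.00748 and 0.0332. Cma1 stood at 9.01 ± 1.05 FPKM (SD, n = 2) in CD24+CD49f+ fMaSC and 74.8 ± 15.9 in CD24low stroma. Pi16, a peptidase inhibitor known from adventitial fibroblasts, fell by 3.36, Cd55, which restrains complement, by 2.50, Efemp1, which encodes the matrix protein fibulin-3, by 2.47 and Akr1c18, an enzyme that inactivates progesterone, by 2.66. Mir692-2, an annotation of 109 bases on chromosome 4 (125504749 to 125504857), was listed at 0 in both CD24+CD49f+ libraries and at 83.1 and 135 FPKM in CD24low stroma. The calls of Pi16, Cd55 and Efemp1 were kept whichever library was left out. Those of Cpa3, Tpsb2, Cma1, Tpsab1, Hdc, Akr1c18 and Mir692-2 all ended without CD24low stroma replicate 1, and all but that of Tpsab1 without replicate 2, with adjusted p of up to 0.194. Those of Tpsb2, Tpsab1, Hdc and Mir692-2 also ended without CD24+CD49f+ fMaSC replicate 1, that of Mir692-2 without replicate 2 and that of Tpsab1 without either Sox10+EpCAM+ library.

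The lists fixed beforehand gave the same picture by cell type. All 18 epithelial junction and identity genes were higher, and all 18 when adjusted over the list alone, with a median log2 fold change of 3.30. Examples are the claudin genes Cldn6 (4.99) and Cldn7 (4.89) and Cdh1 (4.41), which encodes E-cadherin. Camera, limma's competitive test, placed the list above other genes at an adjusted p of 5.8e-22, against adjusted p = 0.116 with an estimated correlation. Of 17 luminal genes 12 rose and 0 fell (15 and 2 adjusted over the list alone), including Cldn4 (5.04) and the luminal transcription factor Gata3 (3.71), with a camera adjusted p of 3.28e-09 (adjusted p = 0.182 with an estimated correlation). Of 19 basal genes 10 rose and 2 fell (11 and 2 adjusted over the list alone). Krt5 (4.37), Krt17 (3.91) and the P-cadherin gene Cdh3 (3.49) led the rise, and camera gave 0.00849 (adjusted p = 0.242 with an estimated correlation). Of 13 glial, neural crest and melanoblast genes 7 rose (8 adjusted over the list alone). They included Erbb3 (3.95), a neuregulin receptor, Mbp (3.94), which encodes myelin basic protein, and Gfra3 (3.19), an artemin co-receptor, with a camera adjusted p of 2.53e-05 (adjusted p = 0.242 with an estimated correlation).

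Part of the stromal genes fell. Of 21 fibroblast and matrix genes 8 were lower (19 adjusted over the list alone), with a median of −1.35 and a camera adjusted p of 3.68e-14 (adjusted p = 0.242 with an estimated correlation). The fibrillin gene Fbn1 (−1.97), Dpt (−1.60), which encodes dermatopontin, and Pdgfrb (−1.63), a growth factor receptor of mesenchyme, were among them. The Pdgfrb call ended without CD24low stroma replicate 1 (adjusted p = 0.0532), the Dpt call without CD24low stroma replicate 2 or either Sox10+EpCAM+ library (up to 0.0693) and the Fbn1 call without any 1 of these 4 libraries (up to 0.125). Of 10 adipocyte genes 5 were lower (8 adjusted over the list alone), including Lpl (−1.58), the lipase that frees fatty acids from lipoproteins, and Plin1 (−1.98), which coats lipid droplets, with a camera adjusted p of 1.14e-08 (adjusted p = 0.116 with an estimated correlation). The Plin1 call ended without CD24low stroma replicate 1 or replicate 2 (adjusted p of up to 0.0708). Globin transcripts stood apart in the CD24+CD49f+ libraries. Hba-a1 was at 1980 and 217 FPKM there and at 26.7 to 58.2 in the other 5 libraries, and 0 of 5 erythroid genes passed limma over all genes while all 5 passed adjusted over the list alone (camera adjusted p = 0.00879, adjusted p = 0.573 with an estimated correlation).

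Signalling genes were mixed. Of 19 FGF and ErbB genes 6 rose (7 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.13), among them the transcription factor gene Etv4 (2.59), the EGF receptor ligand Areg (2.38) and Nrg1 (2.16), which encodes a ligand of ErbB3. Of 11 Wnt genes 2 rose and 2 fell (2 and 2 adjusted over the list alone), with Sfrp1 (2.72), a secreted Wnt inhibitor, and Wnt10b (−1.71) as examples, and the list's median of 0.02 was negative under TPM, TMM and quantile scaling. Of 15 progenitor-linked genes 5 rose (6 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.113), including Lgr5 (2.45), a receptor known from epithelial stem cells, and Bcl11a (2.39). Of 10 embryonic mammary genes 2 rose, Pthlh (4.09), which encodes parathyroid hormone-related protein, and Edar (2.36), the ectodysplasin receptor, and 3 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.423). In all, limma called 1545 of 14418 genes, 1121 higher and 424 lower, and 72.6% of the calls were higher. That share was 52.6% with quantile scaling (855 and 772) and 61.9% with TMM scaling (1019 and 626). A replicate block within this sort, chosen after results were seen, gave 1006 calls (777 higher and 229 lower). The number of calls moved over 1.5-fold without CD24low stroma replicate 1 (589) or replicate 2 (426), without Sox10+EpCAM+ fMaSC replicate 1 (767) or replicate 2 (796), which enter through the shared variance, and without CD24+CD49f+ fMaSC replicate 2 (2353).

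The matching question for the reporter-based sort was which genes separate Sox10+EpCAM+ fMaSC from EpCAM-negative stroma. Epithelial genes were higher and collagen, matrix and fat-cell genes lower, the latter by larger log2 fold changes than in the first comparison. Cytl1 rose by 7.82, to 292 ± 171 FPKM (SD, n = 2) from 0.179 (limma SE 0.54, adjusted p = 0.000444). Csn3 rose by 7.08, Epcam by 6.69, Igfbp2 by 6.37, Sox10 by 6.17 and Krt8 by 6.07. Aldoc, a glycolytic aldolase of nervous tissue, rose by 6.32 (adjusted p = 0.00026). A pair of histone H2B genes on chromosome 13, Hist1h2bm (6.95) and Hist1h2bf (6.03), also rose, although near-identical H2B copies can share reads. The 5S ribosomal RNA annotation n-R5s193 was listed at 95.9 and 78.7 FPKM in Sox10+EpCAM+ fMaSC and at 0 in the other 5 libraries.

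The collagen VI genes Col6a3 (−7.08), Col6a2 (−7.03) and Col6a1 (−7.00) and the fibrillar collagen genes Col1a1 (−7.00), Col1a2 (−6.91) and Col3a1 (−6.66) fell together in Sox10+EpCAM+ fMaSC. Col1a1 stood at 13.2 ± 5.2 FPKM (SD, n = 2) there and at 1750 in EpCAM-negative stroma. Car3, a carbonic anhydrase abundant in fat and muscle, fell by 7.18, Clec3b, which encodes tetranectin, by 6.98, Dpt by 6.79 and Lpl by 6.61 (adjusted p = 0.00093 or lower for these 10 genes). Of 21 fibroblast and matrix genes 20 fell (20 adjusted over the list alone), with a median of −5.43 and a camera adjusted p of 3.92e-17 (adjusted p = 0.208 with an estimated correlation). All 10 adipocyte genes fell (10 adjusted over the list alone), including Adipoq (−6.00), which encodes adiponectin, and Pparg (−4.77), the transcription factor of fat cell formation (camera adjusted p = 5.47e-09, adjusted p = 0.175 with an estimated correlation). Of 14 mesenchymal transcription genes 12 fell and 1 rose (12 and 1 adjusted over the list alone), including Prrx1 (−5.10), Twist2 (−4.93) and Twist1 (−4.75), with a camera adjusted p of 1.23e-07 (adjusted p = 0.289 with an estimated correlation). Of 6 pericyte genes 5 fell (5 adjusted over the list alone), among them Rgs5 (−5.12) and the potassium channel gene Kcnj8 (−4.26), with a camera adjusted p of 0.00229 (adjusted p = 0.208 with an estimated correlation). Of 12 endothelial genes 4 fell (4 adjusted over the list alone), including the angiopoietin receptor gene Tek (−2.52), with a camera adjusted p of 0.0214 (adjusted p = 0.299 with an estimated correlation). Of 4 skeletal muscle genes 3 fell (4 adjusted over the list alone), including Des (−3.01), which encodes desmin, with a camera adjusted p of 0.00328 (adjusted p = 0.299 with an estimated correlation).

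On the epithelial side, all 18 junction genes rose (18 adjusted over the list alone), with a median of 4.11 and a camera adjusted p of 4.12e-16 (adjusted p = 0.185 with an estimated correlation). Spint2 (5.78), Cldn6 (5.74) and Cldn7 (5.52) are examples. Of 17 luminal genes 14 rose and 1 fell (14 and 2 adjusted over the list alone), including Cldn4 (5.89) and Cldn3 (4.62), with a camera adjusted p of 1.23e-07 (adjusted p = 0.208 with an estimated correlation). Of 19 basal genes 12 rose and 3 fell (12 and 3 adjusted over the list alone), with Krt14 at 5.40, Krt17 at 4.84 and Cdh3 at 4.62 and a camera adjusted p of 0.00262 (adjusted p = 0.208 with an estimated correlation). Of 13 glial and melanoblast genes 5 rose and 2 fell (9 and 2 adjusted over the list alone), with Erbb3 at 4.96, Dct, a melanin enzyme, at 3.60 and Ngfr, the low-affinity neurotrophin receptor, at −3.52 (camera adjusted p = 0.0354, adjusted p = 0.42 with an estimated correlation). Among signalling genes, Fgf10 (−4.46), a mesenchymal ligand of mammary bud growth, and Wnt2 (−3.56) fell, and Areg (3.48) and Etv4 (3.36) rose. Of 19 FGF and ErbB genes 6 rose and 6 fell (6 and 6 adjusted over the list alone), and of 11 Wnt genes 2 rose and 4 fell (2 and 4 adjusted over the list alone), with camera adjusted p of 0.389 and 0.206. Of 13 immediate early genes 6 fell and 1 rose (7 and 1 adjusted over the list alone, camera adjusted p = 0.000915, adjusted p = 0.42 with an estimated correlation). Of 11 glycolysis genes 4 rose (6 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0253, adjusted p = 0.27 with an estimated correlation), with Pgk1 at 2.46 and Pkm at 2.40.

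For this pair of groups limma called 3762 genes, 1803 higher and 1959 lower (47.9% higher). Scaling each library to the same sum (TPM) placed the median fold of all genes at −0.63 and called 594 higher and 1619 lower (26.8% higher), while the median of the junction genes relative to all genes was 5.02 under that scaling. The number of calls moved over 1.5-fold without Sox10+EpCAM+ fMaSC replicate 1 (1674) or replicate 2 (1766) and without CD24+CD49f+ fMaSC replicate 1 (5758) or replicate 2 (5745). Of the 80 calls among genes named by rule for this comparison 70 were kept in every fit without 1 library that tested them, those printed above among them. The stroma library could not be left out, and n-R5s193 was not tested without either Sox10+EpCAM+ library.

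**Figure D2:**
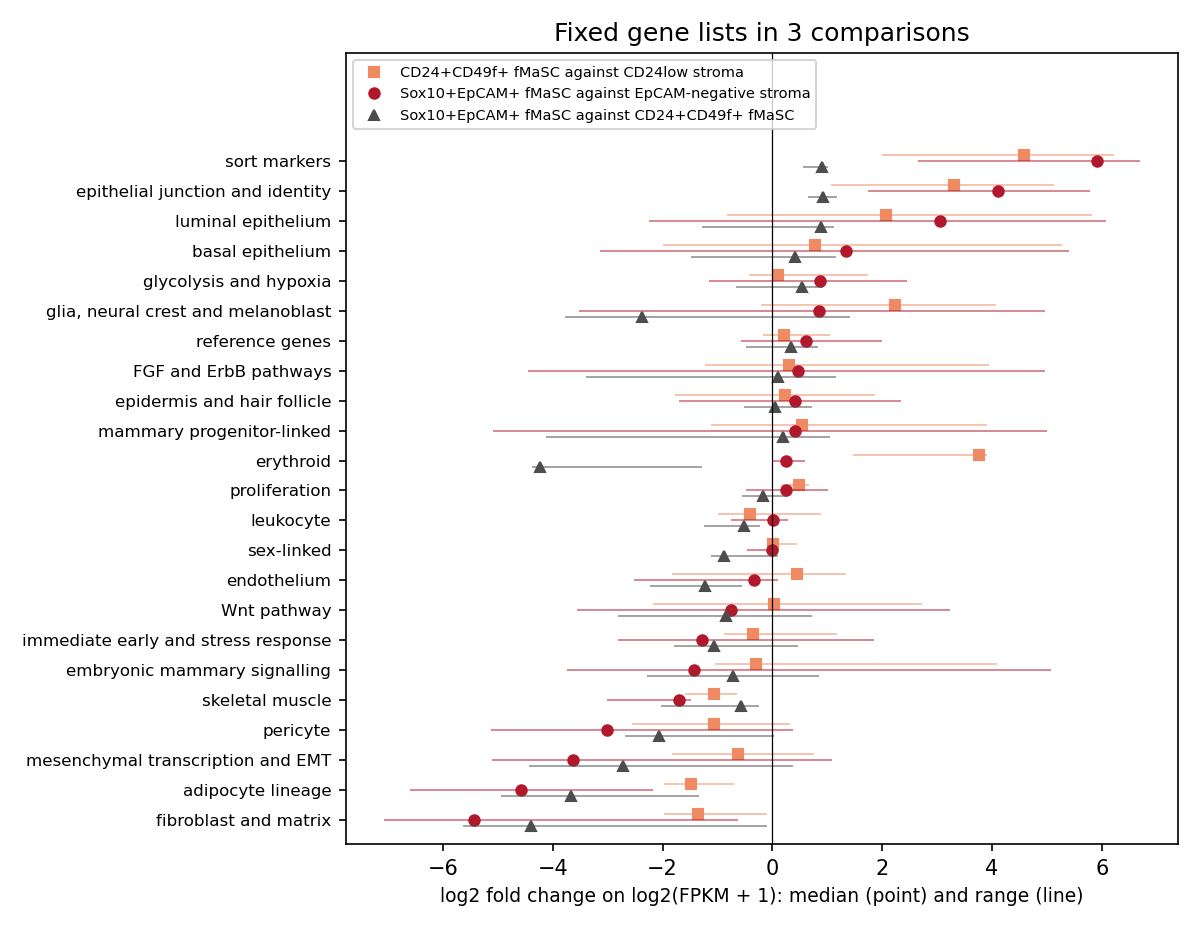
Median (point) and range (line) of the log2 fold changes of the 23 fixed gene lists, on the log2(FPKM + 1) scale, for each sort's fMaSC against its stroma and for Sox10+EpCAM+ against CD24+CD49f+ fMaSC. Junction genes have medians of 3.30, 4.11 and 0.92 in the 3 comparisons, and fibroblast and matrix genes −1.35, −5.43 and −4.39.

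How far both strategies separate the same genes was asked by setting the 2 lists of folds side by side. They share no library, but their tests share the gene variances of the same fit, so numbers for independent lists are a rough guide. Of the genes tested, 978 were higher in the fMaSC of both sorts, where independent lists would share 140, and 391 were lower in both, where independent lists would share 57.6. Across genes the folds correlated with Pearson's r of 0.787 and Spearman's rho of 0.808, and 80.4% had the same sign. The genes called in opposite directions numbered 12, and they were singled out after their values were seen: Cd79a, Fam198b, Gm16265, Gm25541, Gm26397, Ighm, Kcna6, Lgi4, Nefm, Plekha4, Rnu11 and Stard13. Such genes numbered 4 with TPM scaling, and fewer or more depending on the library left out. Nefm encodes a neurofilament and Lgi4 a secreted protein of Schwann cell development. The 1369 shared calls moved over 1.5-fold without CD24low stroma replicate 1 (533) or replicate 2 (395), Sox10+EpCAM+ fMaSC replicate 1 (643) or replicate 2 (667), or CD24+CD49f+ fMaSC replicate 2 (2147).

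**Figure D3:**
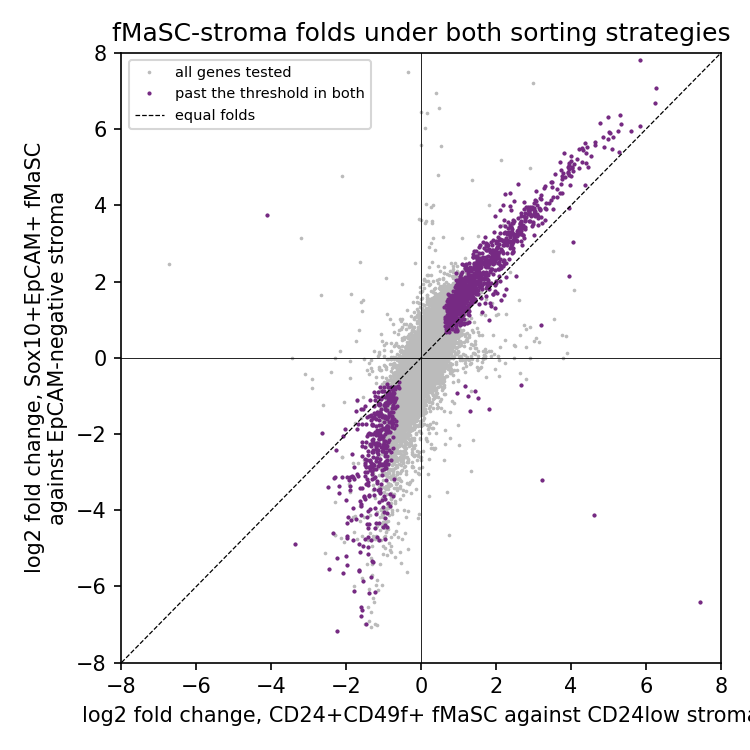
Log2 fold change of each of the 14418 genes tested between fMaSC and stroma in the CD24 and CD49f sort (x axis) and in the Sox10 and EpCAM sort (y axis), 1 point per gene, with genes past the threshold in both coloured. Most coloured points share a sign, 978 higher and 391 lower, and the genes lower in fMaSC lie farther from 0 on the y axis.

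Pooling both strategies asked what fMaSC and stroma differ in when the strategy is taken into account. The genes highest in fMaSC in all 4 libraries were Cytl1 (6.63), Csn3 (6.59), Epcam (6.42), Krt8 (5.93), Krt18 (5.75), Igfbp2 (5.73), Col9a3 (5.53), Aldoc (5.52), Spint2 (5.39) and Sfn (5.38), which encodes the epithelial 14-3-3 protein sigma, with limma adjusted p of 0.000329 or lower. Sfn stood at 103 ± 9.59 and 44.8 ± 6.22 FPKM (SD, n = 2 each) in Sox10+EpCAM+ and CD24+CD49f+ fMaSC, 0.41 ± 0.234 (SD, n = 2) in CD24low stroma and 0.708 in EpCAM-negative stroma. All 18 junction genes rose (18 adjusted over the list alone), with a median of 3.63 and a camera adjusted p of 1.22e-16 (adjusted p = 0.416 with an estimated correlation). Of 17 luminal genes 15 rose and 2 fell (15 and 2 adjusted over the list alone), and of 19 basal genes 11 rose and 2 fell (11 and 5 adjusted over the list alone), with camera adjusted p of 1.54e-07 and 0.00976 (adjusted p = 0.416 and adjusted p = 0.466 with an estimated correlation). Of 13 glial genes 8 rose (8 adjusted over the list alone, camera adjusted p = 0.00749, adjusted p = 0.416 with an estimated correlation), with Erbb3 (4.35) and Mbp (3.22) as examples.

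Lower in fMaSC over both strategies were Pi16 (−3.97), Efemp1 (−3.69), Wnt2 (−2.73), Plin1 (−3.06), Kcnj8 (−2.82), Tek (−2.11) and Wnt10b (−1.47), whose calls held whichever library was left out. Of 21 fibroblast and matrix genes 16 fell (20 adjusted over the list alone), with a median of −3.01 and a camera adjusted p of 5.71e-09 (adjusted p = 0.503 with an estimated correlation). Of 10 adipocyte genes 9 fell (10 adjusted over the list alone, camera adjusted p = 5.15e-06, adjusted p = 0.466 with an estimated correlation). Col1a1 (−3.69) and Lpl (−3.59) had adjusted p of 0.0481 and 0.0353, calls that ended without either Sox10+EpCAM+ library, without CD24+CD49f+ fMaSC replicate 1 or without CD24low stroma replicate 1, and for Col1a1 also without EpCAM-negative stroma, with adjusted p of up to 0.119. Limma called 3621 genes, 2252 higher and 1369 lower (62.2% higher). The share was 49.4% with TPM scaling (792 and 812), 44.7% with quantile scaling (1663 and 2056) and 49.2% with TMM scaling (1760 and 1819), and TPM placed the median of all genes at −0.32. The number of calls moved over 1.5-fold without EpCAM-negative stroma (1563), Sox10+EpCAM+ fMaSC replicate 1 (1687) or replicate 2 (1612), CD24low stroma replicate 1 (2180) or CD24+CD49f+ fMaSC replicate 2 (6374).

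**Figure D4:**
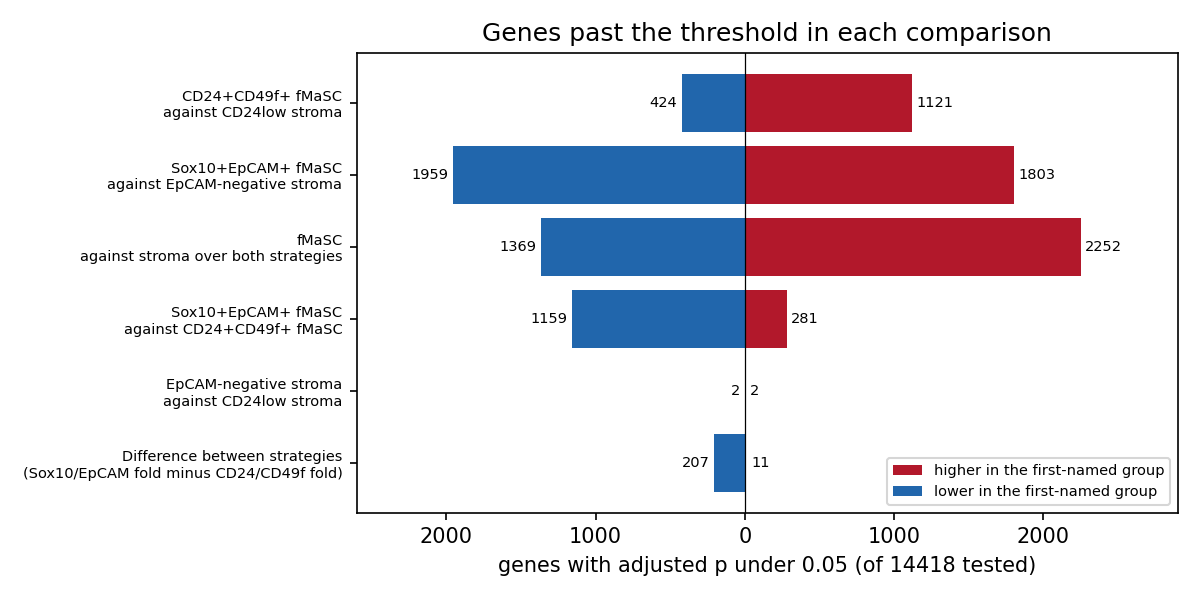
Number of genes called higher and lower by limma in each of the 6 comparisons (bars, genes with an adjusted p under 0.05). The Sox10+EpCAM+ fMaSC against their stroma had the most calls, 1803 higher and 1959 lower. The pooled comparison had the longest bar of genes called higher (2252), and the stroma fractions differed in 2 genes per direction.

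The fMaSC fractions of both sorts were then compared with each other, which addresses the series' question of how the strategies differ. Only the Sox10 and EpCAM sort used the Sox10-Venus reporter, and the column names number the libraries of both sorts in separate ranges. The comparison therefore cannot tell the strategy from the reporter mice or from the library series, and the same holds between the stroma fractions. Matrix, fat-cell, endothelial and glial genes were lower in Sox10+EpCAM+ than in CD24+CD49f+ fMaSC, and epithelial junction genes and 4 named histone H2B genes were higher. Clec3b fell by 6.02, to 0.9 ± 0.466 FPKM (SD, n = 2) from 122 ± 29.6 (limma SE 0.27, adjusted p = 0.000822). Car3 fell by 5.89, Aspn, which encodes the matrix protein asporin, by 5.85, Agtr2, an angiotensin receptor gene, by 5.70, Col1a2 by 5.64, Dpt and Col3a1 by 5.56 each, Dcn, which encodes decorin, and Col1a1 by 5.42 each, and Postn, which encodes periostin, by 5.40 (adjusted p = 0.003 or lower). Of 21 fibroblast and matrix genes 20 were lower (20 adjusted over the list alone), with a median of −4.39 and a camera adjusted p of 4.95e-22 (adjusted p = 0.164 with an estimated correlation). All 10 adipocyte genes were lower (10 adjusted over the list alone), including Adipoq (−4.94) and Lpl (−4.85), with a camera adjusted p of 5.02e-12 (adjusted p = 0.112 with an estimated correlation). Of 14 mesenchymal transcription genes 11 were lower (12 adjusted over the list alone), including Prrx1 (−4.44), Zeb2 (−3.89) and Twist1 (−3.89), with a camera adjusted p of 9.98e-10 (adjusted p = 0.195 with an estimated correlation). The growth factor genes Fgf7 (−3.39), Fgf10 (−3.23) and Fgf18 (−2.28) and the Wnt antagonist gene Dkk2 (−2.81) were lower too. All genes named in this paragraph kept their calls whichever library was left out.

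Other cell-type lists moved with them. Of 13 glial genes 8 were lower in Sox10+EpCAM+ fMaSC (8 lower and 3 higher adjusted over the list alone, camera adjusted p = 0.000777, adjusted p = 0.218 with an estimated correlation). Ngfr (−3.78), Gfra3 (−2.94) and Mbp (−2.83) were among them, and Gfra3 stood at 0.995 ± 0.345 FPKM (SD, n = 2) against 14.2 ± 1.63. Of 12 endothelial genes 8 were lower (12 adjusted over the list alone), including the claudin gene Cldn5 (−2.23) of blood vessels, with a camera adjusted p of 1.46e-07 (adjusted p = 0.164 with an estimated correlation). Of 6 pericyte genes 3 were lower (5 adjusted over the list alone), including the channel subunit gene Abcc9 (−2.28), with a camera adjusted p of 0.00127 (adjusted p = 0.164 with an estimated correlation). Of 5 erythroid genes 1 was lower (5 adjusted over the list alone, camera adjusted p = 0.00201, adjusted p = 0.391 with an estimated correlation). Of 13 immediate early genes 1 was lower (7 adjusted over the list alone, camera adjusted p = 7.14e-05, adjusted p = 0.35 with an estimated correlation), and of 4 muscle genes 1 (2 adjusted over the list alone, camera adjusted p = 0.0399, adjusted p = 0.402 with an estimated correlation). Of 11 Wnt genes 3 were lower (5 adjusted over the list alone, camera adjusted p = 0.0254, adjusted p = 0.399 with an estimated correlation). The Mbp call ended without Sox10+EpCAM+ fMaSC replicate 1 (adjusted p = 0.0606).

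Of 18 junction genes 14 were higher in Sox10+EpCAM+ fMaSC (18 adjusted over the list alone), with a median of 0.92 and a camera adjusted p of 1.24e-13 (adjusted p = 0.164 with an estimated correlation). Spint1 (1.17), which encodes a protease inhibitor, and the epithelial transcription factor genes Ovol1 (1.13) and Grhl2 (1.05) are examples, whose calls ended without Sox10+EpCAM+ fMaSC replicate 1 and without replicate 2 (adjusted p of up to 0.159). Under TPM scaling 0 of the 18 were called, with 13 genes of any kind called higher, and without Sox10+EpCAM+ replicate 1 or replicate 2 also 0, with 23 or 14 of any kind, while 4 were called without CD24low stroma replicate 1 and 4 without replicate 2. Of 17 luminal genes 6 were higher (12 higher and 1 lower adjusted over the list alone, camera adjusted p = 5.05e-06, adjusted p = 0.168 with an estimated correlation) and of 19 basal genes 4 (7 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00201, adjusted p = 0.168 with an estimated correlation). Of these luminal and basal genes 0 were called under TPM scaling or when 1 Sox10+EpCAM+ or 1 CD24low library was left out. The sorting markers had 0 calls in limma (2 adjusted over the list alone). Epcam had a log2 fold change of 1.02 and Sox10 0.86, with adjusted p of 0.0511 and 0.0516, and camera gave the 4 genes 0.00228 (adjusted p = 0.164 with an estimated correlation).

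The genes named by rule as higher in Sox10+EpCAM+ fMaSC included the histone H2B genes Hist1h2bm (7.12), Hist1h2bf (5.86), Hist1h2bb (5.21) and Hist2h2be (2.32), whose near-identical copies can share reads. Hist1h2bm (chromosome 13, 21722098 to 21722478) stood at 231 ± 9.82 FPKM (SD, n = 2) against 0.767 ± 0.799 in CD24+CD49f+ fMaSC. The short annotations n-R5s193 and Mir3074-1 (chromosome 13, 63301180 to 63301296) were listed at 95.9 and 78.7 and at 88.4 and 24.7 FPKM in Sox10+EpCAM+ fMaSC and at 0 in the other 5 libraries. Polr2f (2.13), an RNA polymerase subunit gene, and Pick1 (2.04), which encodes a PDZ-domain trafficking protein, lie on chromosome 15 beside Sox10, at 79141351 to 79151774 and at 79229173 to 79256674. The milk-protein gene Lalba rose by 2.26 and Cytl1 by 2.12. The calls of Polr2f, Lalba and Cytl1 ended without Sox10+EpCAM+ fMaSC replicate 1, those of Polr2f and Lalba without replicate 2, those of Lalba and Cytl1 without either CD24low stroma library, and that of Cytl1 without CD24+CD49f+ fMaSC replicate 2 (adjusted p of up to 0.142). That of Pick1 ended under TPM scaling. Limma called 1440 genes, 281 higher and 1159 lower (19.5% higher). The share was 39.2% with quantile scaling (526 and 816) and 2.45% with TPM scaling (13 and 518), which placed the median of all genes at −0.23, and a pseudocount of 0.1 gave 7.52% (112 and 1377). The number of calls moved over 1.5-fold without Sox10+EpCAM+ fMaSC replicate 1 (269) or replicate 2 (330), CD24low stroma replicate 1 (841) or replicate 2 (850), or CD24+CD49f+ fMaSC replicate 1 (2509).

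Whether the fMaSC-stroma difference itself depended on the strategy was tested as the difference of both folds. This contrast cannot tell the strategy from the reporter mice used in the Sox10 and EpCAM sort. Collagen genes had a far larger fall in the reporter-based sort. The difference of log2 folds was −5.85 for Col6a2, −5.76 for Col6a1, −5.73 for Col6a3, −5.51 for Col1a1 and for Col1a2 and −5.32 for Col3a1 (limma adjusted p between 0.0163 and 0.0369). Clec3b (−5.52), Dpt (−5.19), Lpl (−5.03), Ngfr (−4.22), Twist1 (−3.78), Pparg (−3.28) and Fgf10 (−3.24) also differed. Of 21 fibroblast and matrix genes 15 had a lower fold in the reporter-based sort (20 adjusted over the list alone, camera adjusted p = 1.62e-24, adjusted p = 0.186 with an estimated correlation), as did 5 of 14 mesenchymal transcription genes (11 adjusted over the list alone, camera adjusted p = 2.52e-10, adjusted p = 0.203 with an estimated correlation) and 3 of 10 adipocyte genes (10 adjusted over the list alone, camera adjusted p = 6.16e-11, adjusted p = 0.127 with an estimated correlation). The H2B genes Hist1h2bm (6.56), Hist1h2bf (5.92), Hist1h2bb (5.04) and Hist2h2be (2.47), the bacterial-peptidoglycan binding protein gene Pglyrp1 (1.97) and the peptide transporter gene Slc15a2 (1.82) had higher folds there. Junction genes had a median difference of 0.70 with 0 calls in limma over all genes and 0 adjusted over the list alone (camera adjusted p = 3.77e-10, adjusted p = 0.186 with an estimated correlation). Limma called 218 genes, 11 higher and 207 lower (5.05% higher), against 9 and 50 (15.3%) with TPM scaling, which placed the median of all genes at −0.51. The number of calls fell to 4 without Sox10+EpCAM+ fMaSC replicate 1, 7 without replicate 2, 5 without CD24low stroma replicate 1 and 6 without replicate 2, and was 974 and 397 without CD24+CD49f+ fMaSC replicate 1 and replicate 2. Of the 29 calls among genes named by rule, that of the small nuclear RNA gene Rnu11 held without any 1 of the 6 libraries that could be left out. That of n-R5s193 held in the 4 fits that tested it, none of them without a library that carries it, and the other 27 ended in at least 1 case (adjusted p of up to 0.263).

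The last comparison asked whether the stromal fractions of both sorts differ, with 1 EpCAM-negative library against 2 CD24low libraries. The former was also sorted as Sox10-negative, and the latter were not sorted on Sox10, a gene of glia among others. Limma called 4 genes, all short annotations, named here after their values were seen. Rnu11 (chromosome 4, 132270080 to 132270213) was listed at 16.5 FPKM in EpCAM-negative stroma and at 0 in both CD24low libraries, and the pseudogene Gm16265 at 84.1 FPKM and at 0. The small RNA genes Gm24451 (9.60 and 10.4 FPKM) and Gm25541 (15.8 and 17.0 FPKM) were expressed in the CD24low libraries and listed at 0 in EpCAM-negative stroma. At an unadjusted p under 0.05 there were 436 genes. Mast-cell protease genes stood lower in the EpCAM-negative library, with Cma1 at 4.92 FPKM against 74.8 ± 15.9 (SD, n = 2) and Cpa3 at 2.35 against 49.9 ± 1.25, genes singled out here after their values were seen, and neither passed the test. Of the 23 lists, camera placed 5 apart from other genes, each with 0 called members over all genes in limma. They were the adipocyte (median −0.44, adjusted p = 0.00676), glial (−0.60, 8.85e-06), endothelial (−0.45, 0.000428), leukocyte (−1.15, 0.00676) and embryonic mammary lists (0.36, 0.0224), with adjusted p = 0.374, 0.374, 0.374, 0.98 and 0.98 with an estimated correlation, and 1 leukocyte gene was lower adjusted over the list alone. Fry called 1 list, the adipocyte genes (fry adjusted p = 0.0392). Matrix genes had a median of −0.10, which was 0.18 under TPM and 0.15 under quantile scaling. The number of calls was 0 without CD24low stroma replicate 1 or replicate 2, 9 without Sox10+EpCAM+ fMaSC replicate 1, 7 without CD24+CD49f+ fMaSC replicate 1 and 11 without CD24+CD49f+ fMaSC replicate 2. In simulated data with the same groups, 24.7% of genes changed by 1 on the log2 scale and 94% of those changed by 2 were recovered for this comparison. False calls averaged 7.33 per run. The simulated data held many changed genes, and false calls grow with the number of calls. The 7.33 therefore does not tell how many of the 4 genes called here are false.

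Further lists are given for the fMaSC-stroma comparisons. Of 17 proliferation genes 0 passed limma over all genes or adjusted over the list alone between CD24+CD49f+ fMaSC and CD24low stroma (median 0.49, camera adjusted p = 0.0122, adjusted p = 0.628 with an estimated correlation). Between Sox10+EpCAM+ fMaSC and EpCAM-negative stroma 1 passed, the nucleotide reductase gene Rrm2 (0.99), and 0 adjusted over the list alone (median 0.24, or −0.55 under TPM scaling, camera adjusted p = 0.324), and over both strategies 2 passed and 0 adjusted over the list alone (median 0.38, or −0.05 under TPM scaling, camera adjusted p = 0.0421, adjusted p = 0.627 with an estimated correlation). The Rrm2 call in the reporter-based sort ended without any 1 of the Sox10+EpCAM+ fMaSC or CD24low stroma libraries (adjusted p of up to 0.195). Of 7 leukocyte genes 0 passed in either sort over all genes or adjusted over the list alone (medians −0.40 and 0.01, the latter negative under TPM and TMM scaling, camera adjusted p = 0.213 and 0.742). Of 5 epidermal genes Krt15 (1.87), a keratin of hair follicle progenitors, rose in the CD24 and CD49f sort (1 and 1 adjusted over the list alone, camera adjusted p = 0.981), a call that ended without CD24low stroma replicate 1 or replicate 2 (adjusted p of up to 0.089). In the reporter-based sort 2 of the 5 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.69), and over both strategies 2 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.872). Of the 8 reference genes 0 passed in the CD24 and CD49f sort (1 adjusted over the list alone, median 0.21, negative under TPM and quantile scaling, camera adjusted p = 0.548) and 1 in the reporter-based sort, Gapdh (1.99). The Gapdh call ended without Sox10+EpCAM+ fMaSC replicate 1 (adjusted p = 0.0505), the list's median in that sort was 0.62 and −0.19 under TPM scaling, and camera gave 0.182. Of 3 sex-linked genes 0 passed in either sort over all genes or adjusted over the list alone (medians 0.01 and 0.00, the former negative under quantile and TMM scaling, camera adjusted p = 0.981 and 0.696). Between CD24+CD49f+ fMaSC and CD24low stroma camera also placed 4 lists with few calls below other genes. Of 14 mesenchymal transcription genes 1 fell (1 rose and 5 fell adjusted over the list alone, median −0.62, camera adjusted p = 0.000384, adjusted p = 0.514 with an estimated correlation) and of 6 pericyte genes 2 (3 adjusted over the list alone, median −1.07, camera adjusted p = 0.00165, adjusted p = 0.182 with an estimated correlation). Of 4 skeletal muscle genes 1 fell (4 adjusted over the list alone, median −1.06, camera adjusted p = 0.000597, adjusted p = 0.27 with an estimated correlation), and of 13 immediate early genes 1 rose (1 adjusted over the list alone) at a median of −0.35 (camera adjusted p = 0.0122, adjusted p = 0.628 with an estimated correlation). Of 12 endothelial genes 1 rose and 2 fell (3 and 3 adjusted over the list alone), with a median of 0.45, a mean of 0.13 and a camera adjusted p of 0.981 in the downward direction.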

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

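Of the tests in this part, the split count and the further Schwann-lineage genes were chosen before their results were seen, and all others after. The H2B test is the median of all tested H2B genes, as first written, since a count of called genes would restate what was seen. The test on the Sox10 region leaves out Polr2f and Pick1, which prompted it. Earlier forms of both, which were met, rested on genes already seen, with 5 of 14 H2B genes called and a median of 1.2 over all 7 genes beside Sox10. The test for an unselected stromal sample replaced 2 earlier forms that decided nothing. The first was on the spread of ratios and the second on further mast-cell genes, of which 2 of 8 had a mean of 1 FPKM or more in CD24low stroma. A form on the share of stromal genes alone was met, and the endothelial list was added to it last.

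The CD24+CD49f+ fMaSC libraries carry stromal transcripts that the Sox10+EpCAM+ libraries lack. Fibroblast and matrix genes stood at a median of 31.0% and 50.1% of the CD24low level in replicate 1 and replicate 2, against 0.976% in Sox10+EpCAM+ fMaSC. Stromal cells or their RNA in the CD24+CD49f+ sort may explain this. The 15 junction genes that were low in CD24low stroma had a median ratio of 0.52 to the Sox10+EpCAM+ level, as dilution would give. That ratio restates the junction folds reported above, and the Sox10+EpCAM+ cells were themselves selected on EpCAM. It therefore cannot tell dilution from that selection. Whether such cells could be an unselected sample of CD24low stroma stays open. Of 303 stromal genes 2.97% lay below 0.2 of the CD24low level in both libraries, while 6 mast-cell genes, chosen after they were seen to fall, stood at a median of 10.3% of it. The 2 further mast-cell genes with a mean of 1 FPKM or more in CD24low stroma stood at 38.8% and 73.1% (median 55.9%). The 12 endothelial genes went both ways (1 called higher and 2 lower, median log2 fold change 0.45). A length trend between libraries is unlikely to be the cause, as removing it gave the fibroblast list a median of −4.24 against −4.39.

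Of 13 glial list genes 8 were higher in CD24+CD49f+ than in Sox10+EpCAM+ fMaSC, while 4 had folds in the other direction. CD24low stromal cells are unlikely to have supplied them, because these 8 genes had a median 2.78 log2 units above CD24low stroma. The 8 were chosen for high levels in the same CD24+CD49f+ libraries, which raises that median. All 13 list genes had a median of 2.24 against CD24low stroma, with 7 called higher and 0 lower. Schwann-lineage cells in the sort are a candidate explanation, since 8 of 8 further Schwann-lineage genes were higher in both CD24+CD49f+ libraries than in each of the other 5. No test here separates Schwann cells from a glia-like state of the fMaSC themselves.

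Polr2f and Pick1, beside Sox10, and several H2B genes were higher in the Sox10+EpCAM+ libraries. Whether extra copies of the Sox10 region in reporter mice could explain the first stays open. The 5 other genes within 100000 bases had a median log2 fold change of 0.89 between the fMaSC fractions but 0.03 between the stroma fractions, with 3 of the 5 positive in the latter. Polr2f and Pick1 had 1.40 and 1.59 there without passing the test. Low levels limit this median, as Slc16a8 was at 0.35 FPKM in EpCAM-negative stroma and at 0.101 and 0.0733 in CD24low stroma. Whether reads of an H2B fusion reporter were assigned to H2B genes stays open too. The 14 tested H2B genes had a median of 0.99, under the value of 1 that this was taken to need, set after results were seen. Their folds ran from 0.04 to 7.12, with 5 called higher. A median over all 14 cannot decide the question, since such reads could fall on a few of the copies alone. More replicating cells are a less likely cause, with a median of 0.17 for the other histones and −0.17 for the proliferation list. The labels name the reporter as Sox10-Venus and do not describe its construct.

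As a check on the pooled comparison, the 7 libraries were split into 4 and 3 in all 35 ways with cell type alone in the fit. The true split gave 3381 calls, and 2 of 35 splits gave as many. The other placed both Sox10+EpCAM+ libraries and CD24+CD49f+ fMaSC replicate 1 against the rest (5757). It keeps the 3 stroma libraries together and so shares part of the contrast, the next highest gave 840, and this count by itself does not exclude chance.

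The fMaSC-stroma fold differed between strategies for 218 genes, some of them members of the patterns above. The differences of log2 folds were 6.56 for Hist1h2bm, 6.46 for n-R5s193, 5.92 for Hist1h2bf, 5.58 for Mir3074-1, 5.04 for Hist1h2bb, 2.47 for Hist2h2be, 1.97 for Pglyrp1 and 1.82 for Slc15a2. They were −8.74 for Rnu11, −5.85 for Col6a2, −5.76 for Col6a1, −5.73 for Col6a3, −5.52 for Clec3b, −5.51 for Col1a2, −5.51 for Col1a1, −5.32 for Col3a1, −5.19 for Dpt and −5.16 for Agtr2. The added sequence mL1-GFP_reporter stood at 21.2 and 21.9 FPKM in the Sox10+EpCAM+ libraries and spliced_GFP at 202 and 211. In the other libraries they reached at most 0.0679 and 0.66 FPKM. Only the Sox10+EpCAM+ libraries were sorted as positive for the Sox10-Venus fluorescent reporter.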

How the results depend on the processing

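The tests with the length trend removed, with protein-coding genes alone, without the CD24+CD49f+ libraries and with a replicate block were chosen after results were seen, and the others before. In the 6 comparisons no call of any alternative was opposite in direction to the first analysis. Of 318 called named results 181 were kept under each alternative that covered them and 137 were lost under at least 1, and several alternatives cover part of the genes. For CD24+CD49f+ fMaSC against CD24low stroma (1545 calls) there were 971 with 5 FPKM or more, 556 with TPM scaling, 785 with only the groups compared in the fit, 614 at an adjusted p under 0.01 and 2411 with the length trend removed (1278 higher and 1133 lower, 53% higher). Leaving out Sox10+EpCAM+ replicate 1 or 2 gave 767 or 796, CD24low replicate 1 or 2 589 or 426, and CD24+CD49f+ replicate 2 2353. For Sox10+EpCAM+ fMaSC against EpCAM-negative stroma (3762) there were 2487 with 5 FPKM or more, 2213 with TPM, 7878 with only the groups compared and 1961 at 0.01, and 1674 or 1766 without Sox10+EpCAM+ replicate 1 or 2 and 5758 or 5745 without CD24+CD49f+ replicate 1 or 2. The pooled comparison (3621) had 1604 with TPM, 1841 at 2-fold or more, 1266 at 0.01, 4687 with the length trend removed (2213 higher and 2474 lower, 47.2% higher), 3381 without the strategy term and 5840 without the CD24+CD49f+ libraries. It had 1687 or 1612 without Sox10+EpCAM+ replicate 1 or 2, 1563 without EpCAM-negative stroma, 2180 without CD24low replicate 1 and 6374 without CD24+CD49f+ replicate 2. Between the fMaSC fractions (1440) there were 724 without a filter, 893 with 5 FPKM or more, 531 with TPM, 847 with only the groups compared and 490 at 0.01, and the share called higher was 31% with the length trend removed (667 and 1484). Leaving out Sox10+EpCAM+ replicate 1 or 2 gave 269 or 330, CD24low replicate 1 or 2 841 or 850, and CD24+CD49f+ replicate 1 2509. Between the stroma fractions (4) there were 235 without a filter (229 higher and 6 lower, 97.4% higher, against 2 and 2), 29 with only the groups compared (20 and 9, 69% higher), 0 with the length trend removed and 0 with protein-coding genes alone, and 9 without Sox10+EpCAM+ replicate 1, 7 or 11 without CD24+CD49f+ replicate 1 or 2 and 0 without either CD24low library. The difference between strategies (218) had 421 with a pseudocount of 0.1, 59 with TPM, 104 with quantile scaling, 8 at 0.01, 481 with the length trend removed and 373 with protein-coding genes alone. It had 4 or 7 without Sox10+EpCAM+ replicate 1 or 2, 974 or 397 without CD24+CD49f+ replicate 1 or 2 and 5 or 6 without CD24low replicate 1 or 2. Shared calls of both sorts (1369) numbered 870 without a filter, 895 with 5 FPKM or more, 460 with TPM, 547 at 0.01 and 2113 with the length trend removed, and 643 or 667 without Sox10+EpCAM+ replicate 1 or 2, 2147 without CD24+CD49f+ replicate 2 and 533 or 395 without CD24low replicate 1 or 2. Genes called in opposite directions by both sorts (12) numbered 4 with TPM scaling, 7 with 5 FPKM or more and 4 at an adjusted p under 0.01. Their number fell or rose with the library left out. Fry called 11 of 23 lists for CD24+CD49f+ fMaSC against CD24low stroma and 13 for the reporter-based sort. It called 11 in the pooled comparison, 12 between the fMaSC fractions, 1 between the stroma fractions and 9 for the difference between strategies. In the CD24 and CD49f sort it also called the FGF and ErbB list and the glycolysis list (fry adjusted p = 0.0351 each). There it did not call the mesenchymal, erythroid, proliferation and immediate early lists, which camera did. Camera called 72 of 138 list tests, 0 with an estimated correlation and 41 of 69 without EpCAM-negative stroma. Lists with a negative estimate lost their calls too, such as sort markers (−0.19) and adipocyte genes (−0.104) between CD24+CD49f+ fMaSC and CD24low stroma. Their camera adjusted p went from 3.44e-06 and 1.14e-08 to 0.116 each, so correlation among genes alone does not account for the loss. Camera with an estimated correlation draws on 3 or 4 residual degrees of freedom, and with a preset correlation on the number of genes tested. The loss of all calls therefore reflects low power at least in part, and does not show that gene correlation explains them. For the other shifts the cause was not tested. The labels pair no libraries, but the column names of the CD24 and CD49f sort are written alike by number, so a replicate block within that sort was fitted for CD24+CD49f+ fMaSC against CD24low stroma. It gave 1006 calls against 1545 and ended 9 named calls, those of Tpsb2, Pth1r, Tbx2, Esam, Eno1, Pgk1, Mir692-2, Twist1 and Ier3 (adjusted p of up to 0.111). Ddx3y and Eif2s3y were above 0 in replicate 2 of both groups alone, at 2.42 and 3.74 FPKM in CD24+CD49f+ fMaSC and 2.46 and 3.69 in CD24low stroma. Across genes the differences between numbers in both groups correlated at −0.465, where the length trends between replicates also ran in opposite directions (−0.607 and 0.464), and whether the numbers share an origin was left open.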

Other observations

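The genes and lists in this part were chosen after results were seen, apart from the further Schwann-lineage genes, and no new tests beyond those of the earlier parts were run. Of 8 milk-protein genes 5 passed the filter on low values, and Wap, Csn1s2a and Ltf stayed under 1 FPKM in all libraries. Csn1s1, which encodes alpha-S1-casein, stood at 27.8 and 26.3 FPKM in Sox10+EpCAM+ fMaSC, 11.9 and 7.02 in CD24+CD49f+ fMaSC, 0 and 0.0322 in CD24low stroma and 0.691 in EpCAM-negative stroma. Wfdc18, a whey acidic protein relative, stood at 100 and 82.1, 101 and 21.3, 0.714 and 0.575, and 0.653 FPKM in the same order. Of the 5 milk-protein genes tested, all 5 were higher in CD24+CD49f+ fMaSC than in CD24low stroma (median log2 fold change 3.32) and 4 in Sox10+EpCAM+ fMaSC than in EpCAM-negative stroma (4.57).

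The further Schwann-lineage genes add detail to the glial transcripts of the CD24+CD49f+ libraries. Cnp, a myelin enzyme gene, stood at 37.4 and 21.7 FPKM there, Egfl8 at 30 and 13.3, Ednrb, the endothelin receptor of neural crest, at 12.9 and 13.4, and Dhh, the hedgehog ligand of Schwann cells, at 5.03 and 3.37. Of these 8 genes 7 were higher than in CD24low stroma in limma and 6 were lower in Sox10+EpCAM+ than in CD24+CD49f+ fMaSC.

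Libraries of the same group also differed in Y-linked genes and in a trend on transcript length. Ddx3y and Eif2s3y were listed at 2.42 and 3.74 FPKM in CD24+CD49f+ fMaSC replicate 2, at 2.46 and 3.69 in CD24low stroma replicate 2 and at 0 in the other 5 libraries, and Xist at 59.9 to 145 FPKM in all 7. Across 12257 protein-coding genes, which are not independent replicates, the difference between CD24+CD49f+ replicates correlated with transcript length at −0.607 and that between CD24low replicates at 0.464.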
